A study of Mus musculus with 11 samples.

How the data were processed

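Liver macrophages and monocytes were sorted, per the labels' protocols, after collagenase digestion of livers from Cx3cr1-GFP reporter mice on a C57BL/6 background. For the 3 groups sorted after injury the mice had been fasted and given acetaminophen at 300 mg/kg by gavage. The KCSS arrays are labelled as steady state, with no dose or time of their own, and the protocol also mentions a vehicle without saying which samples received it. Kupffer cells were gated as CD45-positive, CD11b-intermediate cells with MHC class II and CD64, among other macrophage antigens, but no GFP. Ly6Chi monocytes were CD11b-positive, CD64-positive and Ly6C-high with intermediate GFP and no MHC class II, and Ly6Clow macrophages carried CD45, CD11b, MHC class II, CD64 and GFP, among other antigens. Biotin-labelled total RNA was hybridised to Affymetrix arrays. The values are log2 expression per probe set, 1 column per array, which the authors made with RMA, per the submitters' processing notes, and the notes also name Partek 6.6. RMA's background and quantile steps, and the arrays over which they ran, are not given in the sources used here. The columns have similar but not identical quantiles. The replicates' independence is not stated in the labels, so p-values measure the spread between these samples, which may be technical. KCSS has 2 arrays and every other group 3.

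Probe sets were named from the platform annotation, symbols being checked by Entrez identifier against RefSeq genes (assembly GRCm38.p6). Of 35556 probe sets, 21789 had 1 gene symbol, 1621 had several and 12146 are unnamed here. No gene was named from a probe set with several symbols, which leaves Ly6c1 and Ly6c2 unnamed. Entrez identifiers of 21698 probe sets were in the reference, and 0 symbols changed. The 19938 genes were each represented by the probe set with the highest mean over all arrays. Of 999 genes with several probe sets, none had probe sets called in opposite directions in any comparison.

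Group differences were fitted with limma 3.58.1 in R 4.3.3 (lmFit with 1 coefficient per group over all 11 arrays, no block, then eBayes), with Benjamini-Hochberg adjustment over all probe sets within a comparison. A probe set was called at an adjusted p of at most 0.05 and a fold of at least 2, the thresholds in the series' design text. Differences are log2 with their standard error. The 3 main comparisons were Ly6Clow with Ly6Chi, Ly6Clow with KCR and KCR with KCSS, and the other 3 pairs were secondary. Gene list shifts were tested with limma's camera at a preset correlation between genes of 0.01, adjusted over 37 lists of cell type markers and pathways, in which 673 of 726 members were matched (5 by a synonym). camera compares a list with all other genes. limma's fry asks whether a list's genes move, on balance, in the same direction, without comparing them with other genes. The lists, comparisons, thresholds and rule for named genes were set before the data were examined. The rule took the 5 genes with the largest difference in each direction in main comparisons and 3 in secondary ones (called, no overlap between arrays, leaving out predicted, immunoglobulin, T cell receptor and small RNA genes). It also took up to 4 called members of each list that passed, all sort gate and sex-linked genes, up to 2 members of each list of another cell type, and every gene called between KCR and KCSS.

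Replicate numbers are shared between groups. Whether they pair the arrays was checked from the data, since the labels do not say so. Deviations from the group means of arrays with the same number correlated in all 15 pairs (0.203 to 0.692, median 0.55), and those with different numbers ran from -0.677 to 0.616 (median -0.368). Deviations cancel within each group, so positive values for the same number push the others down, and the gap between these medians is partly built in. The median was 0.6685 for pairs of number 1, 0.3125 for number 2 and 0.55 for number 3. A split of number 1 from the rest could therefore account for much of it. Averaged over the arrays of a number, 10 of 11 arrays correlated best with their own number. By single pairs Ly6Chi replicate 3 correlated best with KCSS replicate 2 (0.602, against 0.55 and 0.489 with its own number). The exception by averages was KCSS replicate 2, which correlated at 0.602 to 0.616 with the number 3 arrays and at 0.203 to 0.361 with those of number 2. The deviations of the 2 KCSS arrays mirror each other by construction, so the check is weak for this array and for blocked comparisons with KCSS. As each of the 15 correlations was over 0.1, the numbers were taken to pair the arrays, and a fit with the number as a replicate block was run beside the fit without it, which called 1472 probe sets in place of 1327 between Ly6Clow and Ly6Chi. The blocked value is given beside a result where the block changes its call or moves a count of calls by over 1.5 times.

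The fit was tested on simulated data made from the real spread, with 50 probe sets changed at each fold. Noise was drawn separately for each probe set and array, with no effect shared by arrays of the same number, so rates in the real arrays may differ. A true 2-fold change lies at the fold minimum itself, so its estimates fall on either side of it. Between KCR and KCSS, 72% of 2-fold changes passed the adjusted p and 40% were called, and 92% of 4-fold changes were called. Between Ly6Clow and Ly6Chi 40% of 2-fold and 98% of 4-fold changes were called, and between Ly6Clow and KCR 50% and 98%. For arrays the number of arrays and the signal over background limit precision, and no counting depth applies. The alternatives tried were quantile normalization again, median centring, leaving out dim probe sets (means below 7.871, the median of all values, in each group), probe sets with 1 symbol only, fits of only the groups compared, the replicate block, no moderation, eBayes with trend and robust settings, array weights, other thresholds, and leaving out each array. After the data were seen, fits were added without the number 1 arrays, with number 1 against the others as a block, and without sex-linked probe sets, along with a filter on the genes that set the position of Ly6Clow. A range over the alternatives given for a list covers camera's fits, and fry, which asks another question, is left out of it. That position is the median over genes of the array minus the Ly6Chi mean, divided by the KCR mean minus the Ly6Chi mean. Tables were handled with Python 3.11.15, numpy 2.4.6 and pandas 2.3.3, and plots drawn with matplotlib 3.10.9.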

Results

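Gene expression was measured with Affymetrix arrays in macrophages sorted from the livers of Cx3cr1-GFP reporter mice around acetaminophen (APAP) overdose, which kills hepatocytes and draws blood monocytes into the liver. The 11 arrays fell into 4 groups. Kupffer cells, the resident macrophages of the liver sinusoids, came from steady-state livers (KCSS, n = 2) and from livers recovering at 72 h (KCR, n = 3). Infiltrating Ly6C-high monocytes (Ly6Chi, n = 3) were sorted at 24 h, and Ly6C-low macrophages that the labels call monocyte-derived (Ly6Clow, n = 3) at 72 h. The dose was 300 mg/kg. Each array held 35556 probe sets on a log2 scale, with array medians from 7.83 to 7.97, and the number of arrays limits the precision. The values carry no detection call. Of the called genes taken by the rule for named genes, the lower group mean lay under the dim limit of 7.871, the median of all values, in 27 of 78 between Ly6Clow and Ly6Chi, 8 of 38 between Ly6Clow and KCR and 5 of 12 between KCR and KCSS. Their log2 differences are fitted values against a signal not shown to be above background, and so are their ranks. Pearson correlations over all probe sets ran from 0.975 to 0.996 within groups and from 0.937 to 0.993 between groups (medians 0.985 and 0.968). Component 1 of the variance (49.4%) placed Kupffer cells opposite Ly6Chi, with Ly6Clow between them. Component 2 (21.1%) separated the arrays numbered 1 from those numbered 2 and 3 in all 4 groups.

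**Figure D1:**
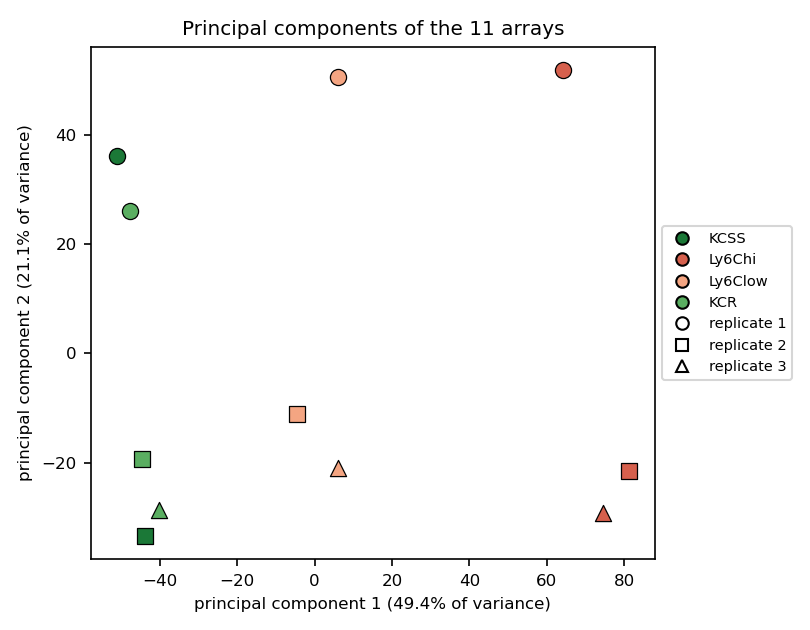
Each point is an array placed on principal components 1 (49.4% of the variance) and 2 (21.1%) of the log2 values of 35556 probe sets; colour gives the group and shape the replicate number. Ly6Chi arrays lie at the right, both Kupffer cell groups at the left and Ly6Clow between them, while replicate 1 of every group lies at the top.

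Genes that encode the sorting markers differed between groups, in part along the gates. Itgam (CD11b) was lower in Ly6Clow than in Ly6Chi by a log2 difference of -1.91 ± 0.23 (SE) and higher in Ly6Clow than in KCR by 1.42 ± 0.23 (limma adjusted p = 0.000777 and 0.00769). The gates for Ly6Chi and Ly6Clow both required CD11b, so the first difference does not follow them. Itgam was 10.57 and 11.18 on the KCSS arrays, gated as CD11b-intermediate, and 11.36 to 11.83 on those of Ly6Clow. H2-Ab1, an MHC class II chain, was higher in Ly6Clow than in Ly6Chi by 1.87 ± 0.16 (adjusted p = 0.000153). Cx3cr1, whose reporter defined the gates, exceeded KCR by 3.75 ± 0.54 in Ly6Clow and by 2.87 ± 0.54 in Ly6Chi (adjusted p = 0.00455 and 0.00526). Adgre1, which encodes a macrophage surface antigen, differed by -1.12 ± 0.27 between Ly6Chi and KCR and by -1.25 ± 0.30 between Ly6Chi and KCSS (adjusted p = 0.0171 and 0.0187). Its difference was -0.73 and -0.86 without Ly6Chi replicate 2, and -0.97 from KCR with array weights, below the fold minimum. The call was lost without KCR replicate 3 for KCR (adjusted p = 0.0577), for KCSS without KCSS replicate 1 or 2 (0.0862 and 0.096), and for both with only the 2 groups fitted (0.0745 and 0.157). Over the alternatives its adjusted p ran from 0.000179 to 0.0858 for KCR and from 0.000131 to 0.157 for KCSS. Without the number 1 arrays the adjusted p of Itgam between Ly6Clow and KCR was 0.0918 (0.00274 to 0.0918 over the alternatives). That of Cx3cr1 was then 0.0791 for Ly6Clow and 0.0801 for Ly6Chi (from 1.68e-05 and 9.98e-06 upward over the alternatives). Ly6Chi replicate 2 stood at 9.94 for Cx3cr1, against 12.46 and 12.04 in replicates 1 and 3. Ptprc (CD45) and Fcgr1 (CD64) passed in no comparison, with the largest log2 difference of Fcgr1 at 0.28 between Ly6Clow and KCR. Among sex-linked genes, KCSS replicate 1 carried Xist at 12.31, where the other 10 arrays lay between 5.65 and 6.14. Kdm5d was 6.58 on that array and 9.93 to 10.49 on the others, and Eif2s3y and Uty were low there as well (5.79 and 5.70).

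Ly6Clow macrophages at 72 h were compared with the infiltrating Ly6Chi monocytes at 24 h. Whether Ly6Clow descend from Ly6Chi was not tested. In Ly6Clow macrophages 16 of 22 Kupffer cell, 27 of 35 cell cycle and 6 of 14 MHC class II genes were called higher, along with 2 MHC class II genes lower. Ly6Chi were sorted without MHC class II and Ly6Clow with it, so a rise of MHC class II genes follows the gates. Called lower were 12 of 17 inflammatory monocyte, 12 of 20 inflammatory cytokine and 13 of 22 glycolysis and hypoxia genes. Each of these lists passed camera, but with an estimated correlation the Kupffer cell list alone among them did so (adjusted p = 0.0191, and from 0.0788 to 0.152 for the others). Cd5l, a secreted scavenger receptor family protein of tissue macrophages, averaged 13.20 ± 0.21 in Ly6Clow and 7.95 ± 0.47 in Ly6Chi (SD, n = 3 each), a 38.1-fold difference. Vcan, the matrix proteoglycan versican, went the other way, at 7.50 ± 0.42 in Ly6Clow, below the dim limit, against 13.62 ± 0.26 in Ly6Chi. limma called 1327 probe sets (806 higher and 521 lower), which included 1018 genes. The largest rises were those of Cd5l (5.25 ± 0.21, adjusted p = 2.96e-06), the vacuolar proton pump subunit Atp6v0d2 (5.00 ± 0.44, adjusted p = 0.000167) and the complement receptor Vsig4 (4.75 ± 0.20, adjusted p = 3.73e-06). Ccna2 and the lectin receptor Clec1b followed at 4.19 ± 0.20 and 3.96 ± 0.16. The largest falls were those of Vcan (-6.11 ± 0.23, adjusted p = 2.82e-06), the lipocalin Lcn2 (-5.59 ± 0.38, adjusted p = 4.72e-05) and the acute-phase protein Saa3 (-5.43 ± 0.31, adjusted p = 2.07e-05), then Serpinb10 (-5.25 ± 0.32) and the calprotectin subunit S100a8 (-4.96 ± 0.31).

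Of 37 gene lists, 21 shifted in camera, which compares a list with all other genes, 15 upward and 6 downward. Only the Kupffer cell and clearance lists kept the call when the correlation between genes was estimated, and counts adjusted over the list alone are given where they differ. Of 22 measured Kupffer cell markers, 16 rose and none fell (median 1.56, adjusted p = 4.18e-18, adjusted p = 0.0191 with an estimated correlation). Folr2, a folate receptor, rose by 3.85 ± 0.44. Of 24 clearance and scavenger receptor genes, 6 rose, or 7 adjusted over the list alone (adjusted p = 8.73e-05, adjusted p = 0.0447 with an estimated correlation), among them Gas6, which bridges dying cells to phagocyte receptors (3.03 ± 0.32), Mrc1 (1.99 ± 0.18) and Scarf1 (1.59 ± 0.09). Of 35 cell cycle genes, 27 rose (median 1.49, adjusted p = 1.98e-27, adjusted p = 0.0966 with an estimated correlation), with Ccnb2 12.1-fold higher, Plk1 at 3.25 ± 0.28 and Kif11 at 2.98 ± 0.19. Among 17 inflammatory monocyte markers 12 fell (median -1.83, adjusted p = 2.06e-10, adjusted p = 0.0788 with an estimated correlation), including Hp (-4.09 ± 0.36) and Clec4e (-3.84 ± 0.25). Among 20 inflammatory cytokines and mediators 12 fell, or 14 adjusted over the list alone (adjusted p = 2.42e-08, adjusted p = 0.122 with an estimated correlation), with Trem1, an amplifier of inflammatory signalling, at -4.87 ± 0.33 and Il6 at -4.08 ± 0.71. Among 22 glycolysis and hypoxia genes 13 fell, or 14 adjusted over the list alone (median -1.20, adjusted p = 4.71e-11, adjusted p = 0.152 with an estimated correlation). These included the oxygen sensor Egln3 (-4.56 ± 0.43), the lactate exporter Slc16a3 (-2.89 ± 0.14) and the glucose transporter Slc2a1 (-2.48 ± 0.17).

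Lipid and cholesterol handling shifted upward with 7 of 20 genes (adjusted p = 5.83e-06, adjusted p = 0.0966 with an estimated correlation), led by the desaturase Scd1 (3.03 ± 0.36) and the phospholipid transfer protein Pltp (2.78 ± 0.08). The list's median of 0.81 was 0.45 without Ly6Chi replicate 2. Of 14 MHC class II presentation genes 6 rose and 2 fell (adjusted p = 0.0022, adjusted p = 0.0788 with an estimated correlation), with H2-Eb1 at 2.56 ± 0.25 and H2-Aa at 1.90 ± 0.19. The gates differ in MHC class II, so this rise is not independent of the sort. Of 22 growth and angiogenic factors 8 rose and 2 fell (median 0.44, or 0.24 without Ly6Clow replicate 2 and 0.88 without dim probe sets, adjusted p = 0.00228, adjusted p = 0.0788 with an estimated correlation). Pdgfc, a growth factor for mesenchymal cells, rose by 3.41 ± 0.12 and Vegfa fell by 3.33 ± 0.27. Of 18 complement genes 7 rose and 1 fell (adjusted p = 0.00103, adjusted p = 0.0788 with an estimated correlation), including C6 (2.08 ± 0.08). Of 23 interferon response genes 10 rose, or 14 adjusted over the list alone (adjusted p = 4.25e-08, adjusted p = 0.354 with an estimated correlation), with Ifit2 at 3.22 ± 0.37 and Ifit3 at 2.88 ± 0.35. Their median of 1.16 was 0.77 without Ly6Chi replicate 2. Of 15 core macrophage genes 5 rose and 1 fell, or 6 and 1 adjusted over the list alone (adjusted p = 2.86e-06, adjusted p = 0.122 with an estimated correlation), with C1qa at 2.38 ± 0.32 and the endotoxin co-receptor Cd14 at -1.57 ± 0.22. Lysosomal hydrolases shifted upward with 1 of 22 called, Glb1 (1.39 ± 0.18), or 2 adjusted over the list alone and 2 with the replicate block (adjusted p = 3.97e-06, adjusted p = 0.228 with an estimated correlation). Oxidant defence genes shifted downward with 3 of 18 called (adjusted p = 0.000118, adjusted p = 0.0788 with an estimated correlation), led by the cystine carrier Slc7a11 (-4.40 ± 0.35). Trem2-associated lipid macrophage genes rose in 3 of 16 (adjusted p = 0.0242, adjusted p = 0.42 with an estimated correlation), with Fabp5 at 1.60 ± 0.26 and Gpnmb at 1.49 ± 0.25, and their adjusted p was 0.0538 without Ly6Chi replicate 2, 0.183 without dim probe sets and 0.19 with dim genes out of the background (0.00982 to 0.42 over the alternatives). Of 8 Fc receptors 2 rose, Fcrls (2.27 ± 0.38) and Fcer2a (2.11, adjusted p = 0.029, and 0.00556 to 0.0793 over the alternatives). Fcer2a stood at 10.1 in Ly6Clow replicate 2, against 7.95 and 8.93 in replicates 1 and 3, a pattern shared with the B cell marker Ms4a1. The Fc receptors as a list had an adjusted p of 0.0351, and of 0.134 with an estimated correlation. Their adjusted p was 0.0825 without Ly6Chi replicate 1, 0.0505 without Ly6Chi replicate 3, 0.0931 without the number 1 arrays, 0.122 without dim probe sets, 0.0575 with only the 2 groups fitted and 0.19 with dim genes out of the background (0.0211 to 0.19 over the alternatives), and that of Fcrls itself was 0.051 without the number 1 arrays (0.000888 to 0.051).

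Markers of other cell types moved in this comparison too. Sinusoidal endothelial markers rose in 9 of 20 genes, or 14 adjusted over the list alone (median 1.56, adjusted p = 2.86e-06, adjusted p = 0.396 with an estimated correlation). Among them Ehd3 stood at 12.59 in Ly6Clow replicate 2, against 10.32 and 11.20 in replicates 1 and 3. B cell markers rose in 4 of 15, or 6 adjusted over the list alone (adjusted p = 8.38e-05, adjusted p = 0.387 with an estimated correlation), with Cd79b at 2.64 ± 0.35. Ms4a1 (CD20) was 10.14 in that same Ly6Clow array and 7.80 and 8.73 in the others. Neutrophil markers fell in 6 of 18 (adjusted p = 4.61e-06, adjusted p = 0.122 with an estimated correlation), including the decoy receptor Il1r2 (-4.56 ± 0.72) and the protease inhibitor Slpi (-3.58 ± 0.15). Their median of -0.58 was -0.27 without Ly6Chi replicate 2, where Il1r2 reached 13.55, and -1.97 without dim probe sets. Dendritic cell markers rose in 4 of 18 and fell in 1 (adjusted p = 0.00159, adjusted p = 0.148 with an estimated correlation), with Clec9a at 3.64 ± 0.26 and Cd209a at 2.43 ± 0.44 (adjusted p = 0.00641, 0.0571 without the number 1 arrays, and 0.000622 to 0.0571 over the alternatives). Clec9a was brighter still in Kupffer cells (12.57 and 11.94 in KCSS, 10.1 to 10.74 in Ly6Clow), so its rise need not mark dendritic cells. Dissociation and heat shock genes fell in 4 of 20 (adjusted p = 0.000341, adjusted p = 0.387 with an estimated correlation), with Socs3 at -2.43 ± 0.44 and Ier3 at -1.88 ± 0.17. T and NK cell markers, with 1 of 20 called (Klrd1, 1.33 ± 0.13), had an adjusted p of 0.0531, and 0.0293 with the replicate block. They passed without either KCSS array (0.0235), Ly6Clow replicate 1 or 3 (0.0066 and 0.0295), KCR replicate 3 (0.0454) or the number 1 arrays (0.00252), and their range over the alternatives was 0.00252 to 0.711. The other 15 lists did not pass (adjusted p from 0.0599 for chemokine receptors to 0.986 for alternative activation genes). Chemokine receptors (median -0.44, 0.0119 to 0.354 over the alternatives) passed without either KCSS array (0.0396), Ly6Chi replicate 2 (0.0119), Ly6Clow replicate 2 (0.0369) or KCR replicate 3 (0.0498). Ly6C-low blood monocyte markers passed without Ly6Chi replicate 2 (median -0.27 in place of 0.04, adjusted p = 0.0307, and 0.0307 to 0.898 over the alternatives). Matrix proteases and their inhibitors were among these, with 5 higher and 7 lower of 20, and so were hepatocyte, stellate cell, erythroid and platelet markers. For 5 of them, the Ly6C-low blood monocyte, hepatocyte, oxidative phosphorylation, alternative activation and transcription factor lists, the median, the mean and camera's direction differed in sign. The endothelial list holds 1 gene each of the Kupffer cell (Cdh5), growth factor (Bmp2), clearance (Stab2) and Fc receptor (Fcgr2b) lists. The neutrophil list holds 2 of the protease list (Mmp8 and Mmp9) and 1 each of the cytokine and iron (Lcn2 in both), chemokine receptor (Cxcr2), alternative activation (Il1r2) and oxidant defence (Mpo) lists. The B cell and dendritic cell lists share 1 gene (Ly6d), the dendritic cell and transcription factor lists 1 (Irf4), and the platelet and chemokine lists 1 (Pf4). Overlaps among the macrophage lists are not given here. They do occur, as C6 is in both the Kupffer cell and complement lists, so list results need not be independent.

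**Figure D2:**
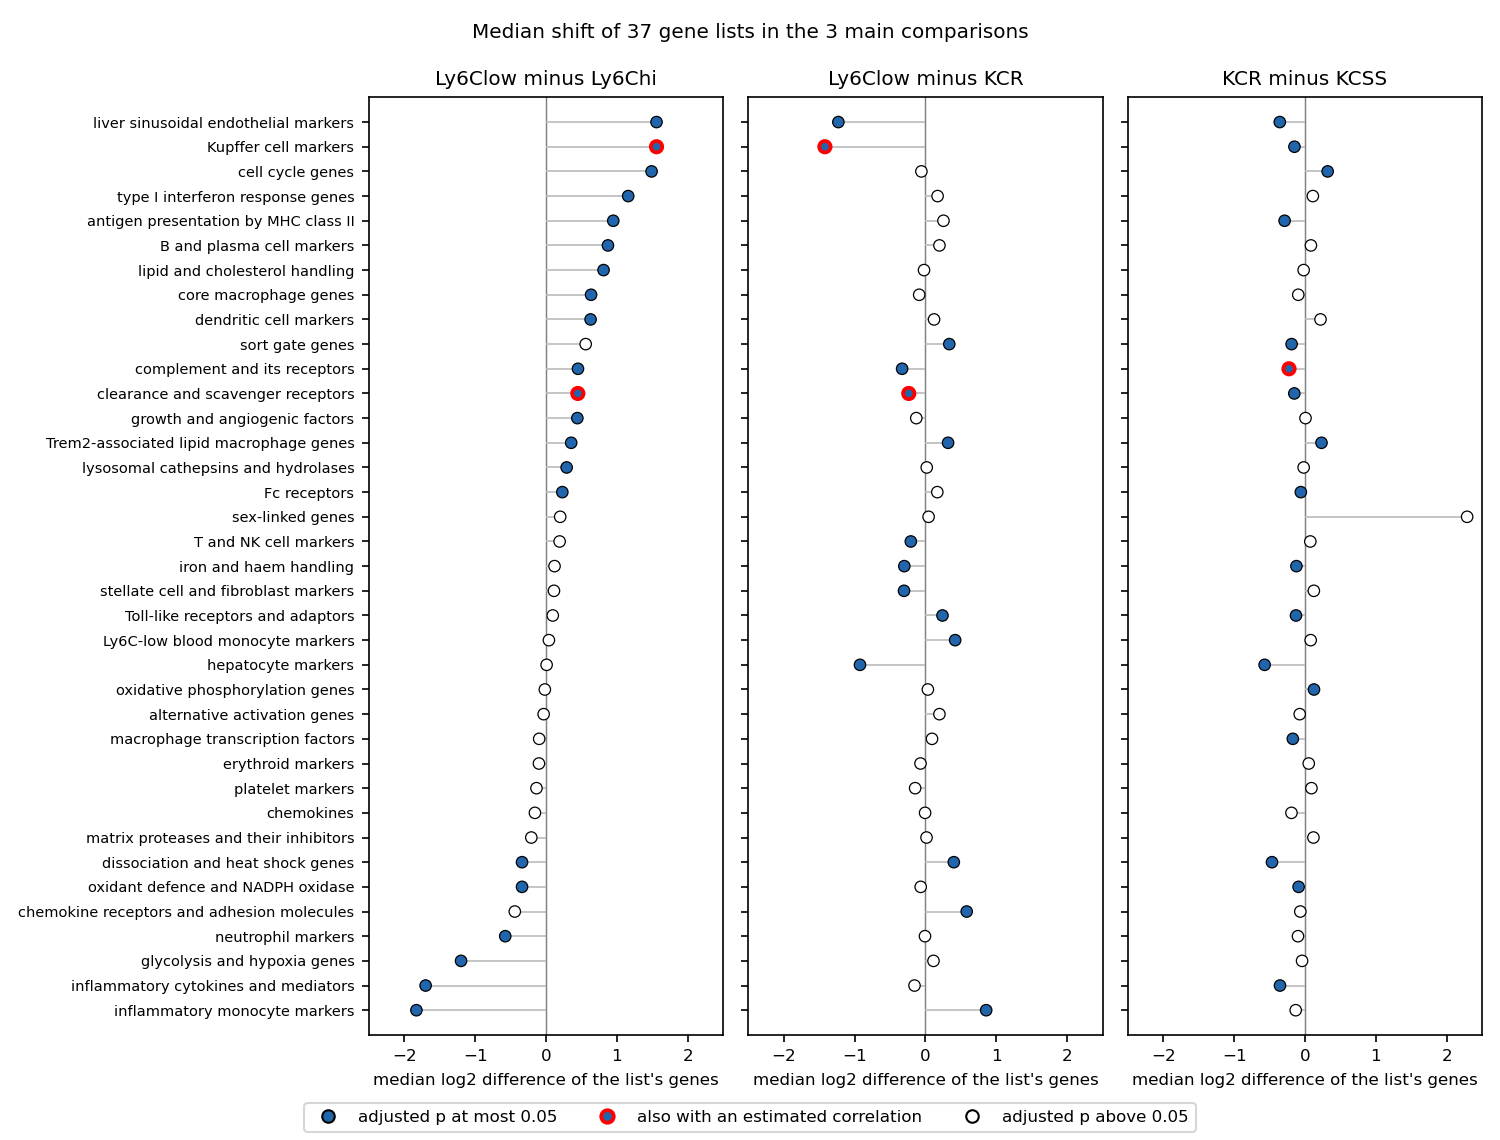
Each point is the median log2 difference over a list's genes, one panel per main comparison; filled points have a camera adjusted p of at most 0.05, and a red edge marks those that also pass with an estimated correlation. Kupffer cell markers stand at 1.56 in Ly6Clow minus Ly6Chi and at -1.42 in Ly6Clow minus KCR.

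The comparison of Ly6Clow with KCR set 2 macrophage populations sorted at 72 h side by side. In Ly6Clow 7 of 17 inflammatory monocyte markers and 6 of 18 chemokine receptor and adhesion genes were called higher, with 1 of the latter lower. Called lower were 12 of 22 Kupffer cell and 5 of 24 clearance genes, with 1 of the latter higher. With an estimated correlation the Kupffer cell and clearance lists passed (adjusted p = 0.0124 and 0.0391), and the monocyte and chemokine receptor lists did not (adjusted p = 0.126 and 0.0862). The chitinase-like protein Chil3 was 11.70 ± 0.33 in Ly6Clow and 7.10 ± 0.97 in KCR, and the complement component C6 was 8.77 ± 0.13 and 13.16 ± 0.09 (SD, n = 3 each). limma called 601 probe sets (284 higher and 317 lower in Ly6Clow), with 499 genes. The largest differences upward were those of Chil3 (4.60 ± 0.50, adjusted p = 0.00082), Gpr141 (4.21 ± 0.22, adjusted p = 8.52e-06), the coagulation factor subunit F13a1 (4.16 ± 0.46), Sh2d1b1 (4.11 ± 0.38) and Emb (adjusted p = 5.19e-05). Downward they were those of the B cell attractant Cxcl13 (-4.64 ± 0.18, adjusted p = 1.44e-06), Pcolce2 (-4.47 ± 0.10), C6 (-4.39 ± 0.08, adjusted p = 4.98e-08), Paqr9 (-4.35 ± 0.11) and the potassium channel Kcnj16 (-4.30 ± 0.11). In camera 15 lists passed, and again the Kupffer cell and clearance lists alone did so with an estimated correlation. Genes that these lists may share were not taken out, so the results for both need not be independent. Of 22 Kupffer cell markers 12 were lower, or 13 adjusted over the list alone (median -1.42, adjusted p = 1.65e-20, adjusted p = 0.0124 with an estimated correlation). Timd4, which binds phosphatidylserine on dying cells, differed by -4.08 ± 0.16. Among 24 clearance genes 5 were lower and 1 higher, or 6 and 2 adjusted over the list alone (adjusted p = 0.000102, adjusted p = 0.0391 with an estimated correlation), with Marco at -3.60 ± 0.11 and Cd209f at -3.22 ± 0.20. The haemoglobin scavenger receptor Cd163 differed by -3.87 ± 0.62 (adjusted p = 0.00811, 0.107 without the number 1 arrays, and 2.65e-05 to 0.107 over the alternatives).

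Inflammatory monocyte markers were higher in Ly6Clow than in KCR for 7 of 17 genes, or 8 adjusted over the list alone (median 0.86, adjusted p = 1.6e-07, adjusted p = 0.126 with an estimated correlation), with the chemokine receptor Ccr2 at 3.86 ± 0.35 and Thbs1 at 3.51 ± 0.23. Chemokine receptors and adhesion molecules were higher for 6 of 18 and lower for 1 (adjusted p = 4.08e-05, adjusted p = 0.0862 with an estimated correlation), including Ccr1 (3.71 ± 0.30) and the integrin Itgax (1.81 ± 0.19). Ly6C-low blood monocyte markers were higher for 3 of 11 (adjusted p = 0.0079, adjusted p = 0.532 with an estimated correlation), with Ace at 2.49 ± 0.22. Their adjusted p was 0.0719 without dim probe sets and 0.0745 with dim genes out of the background (0.00344 to 0.532 over the alternatives). Trem2-associated genes were higher for 4 of 16, or 5 adjusted over the list alone (adjusted p = 4.47e-05, adjusted p = 0.213 with an estimated correlation), with the fatty acid carrier Fabp5 at 2.92 ± 0.26 and Gpnmb 2.83-fold higher. The sort gate list passed with 2 of 6 higher (adjusted p = 0.00308, adjusted p = 0.0862 with an estimated correlation). Toll-like receptors and adaptors passed with 1 of 19 higher (adjusted p = 0.00121, adjusted p = 0.0858 with an estimated correlation). Iron and haem genes were lower for 3 of 19 (adjusted p = 0.0129, adjusted p = 0.398 with an estimated correlation). Complement genes split into 3 higher and 4 lower of 18, or 3 and 6 adjusted over the list alone. Their adjusted p was 0.05, and it was 0.075 with the replicate block and 0.188 with an estimated correlation (0.013 to 0.188 over the alternatives). It was also 0.078 without KCSS replicate 1 or 2, 0.0568 without Ly6Chi replicate 1, 0.11 without Ly6Clow replicate 3, 0.112 without KCR replicate 2, 0.0565 with array weights, 0.0837 with number 1 against the others as a block and 0.0503 with genes taken as the mean of their probe sets. Of 23 interferon genes limma called 0, with 2 at an unadjusted p under 0.05 (list adjusted p = 0.0738, and 0.0461 with the replicate block). That list passed without Ly6Chi replicate 2 (0.0258), and without Ly6Clow replicate 3 (0.00175) or KCR replicate 1 (0.00509), where its median of 0.17 was 0.33 and 0.34 (0.00175 to 0.848 over the alternatives).

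Hepatocyte markers were lower in Ly6Clow than in KCR for 6 of 18 genes (median -0.93, adjusted p = 3.42e-10, adjusted p = 0.188 with an estimated correlation), with Ahsg at -1.84 ± 0.24 and albumin, Alb, at -1.80 ± 0.21. Without the number 1 arrays the adjusted p of Ahsg was 0.0665 (0.000234 to 0.0665 over the alternatives). Sinusoidal endothelial markers were lower for 2 of 20, or 6 adjusted over the list alone (adjusted p = 3.02e-05, adjusted p = 0.553 with an estimated correlation). Their median of -1.23 was -1.88 without Ly6Clow replicate 2, -0.68 without Ly6Clow replicate 1, -0.81 without the number 1 arrays and -0.82 with array weights. Stellate cell markers shifted downward with 0 of 18 called in limma and 12 at an unadjusted p under 0.05, or 3 called adjusted over the list alone (adjusted p = 0.000115, adjusted p = 0.188 with an estimated correlation). Their median of -0.30 was -0.20 without KCR replicate 3, and the matrix proteoglycan Bgn differed by -1.17 ± 0.31 (adjusted p = 0.0768, and 0.0154 with the replicate block, under which 1 of the 18 was called). T and NK cell markers shifted downward with 0 of 20 called in limma and 10 at an unadjusted p under 0.05 (adjusted p = 0.00559, adjusted p = 0.689 with an estimated correlation). Their adjusted p was 0.0777 without KCR replicate 2 (8.03e-05 to 0.689 over the alternatives), and their median of -0.21 was -0.31 without Ly6Clow replicate 2 and -0.43 without dim probe sets. Dissociation and heat shock genes were higher for 2 of 20 (adjusted p = 0.000177, adjusted p = 0.48 with an estimated correlation), and their median of 0.40 was 0.21 without the number 1 arrays. The other 22 lists did not pass (adjusted p from 0.0738 to 0.997). They included cell cycle genes, where limma called 0 of 35 and 1 had an unadjusted p under 0.05 (median -0.06, list adjusted p = 0.63, and 0.0181 to 0.967 over the alternatives), the MHC class II list with 1 of 14 lower, the inflammatory cytokine list with 2 higher and 1 lower of 20 (1 higher with the replicate block), and neutrophil markers, where Mmp8 alone was called higher (3.58 ± 0.26). Of the 22, 7 passed in an alternative, each without at least 1 array. Besides the interferon list these were B cell markers without Ly6Clow replicate 1 or the number 1 arrays (medians 0.53 and 0.44 in place of 0.20), and neutrophil markers without KCR replicate 1 or the number 1 arrays (0.11 and 0.13 in place of -0.01). The others were cell cycle (-0.16) and lysosomal genes without KCR replicate 3, transcription factors without KCR replicate 2 or 3, and core macrophage genes without Ly6Chi replicate 2. The neutrophil and chemokine lists were the 2 whose median, mean and camera direction differed in sign.

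**Figure D3:**
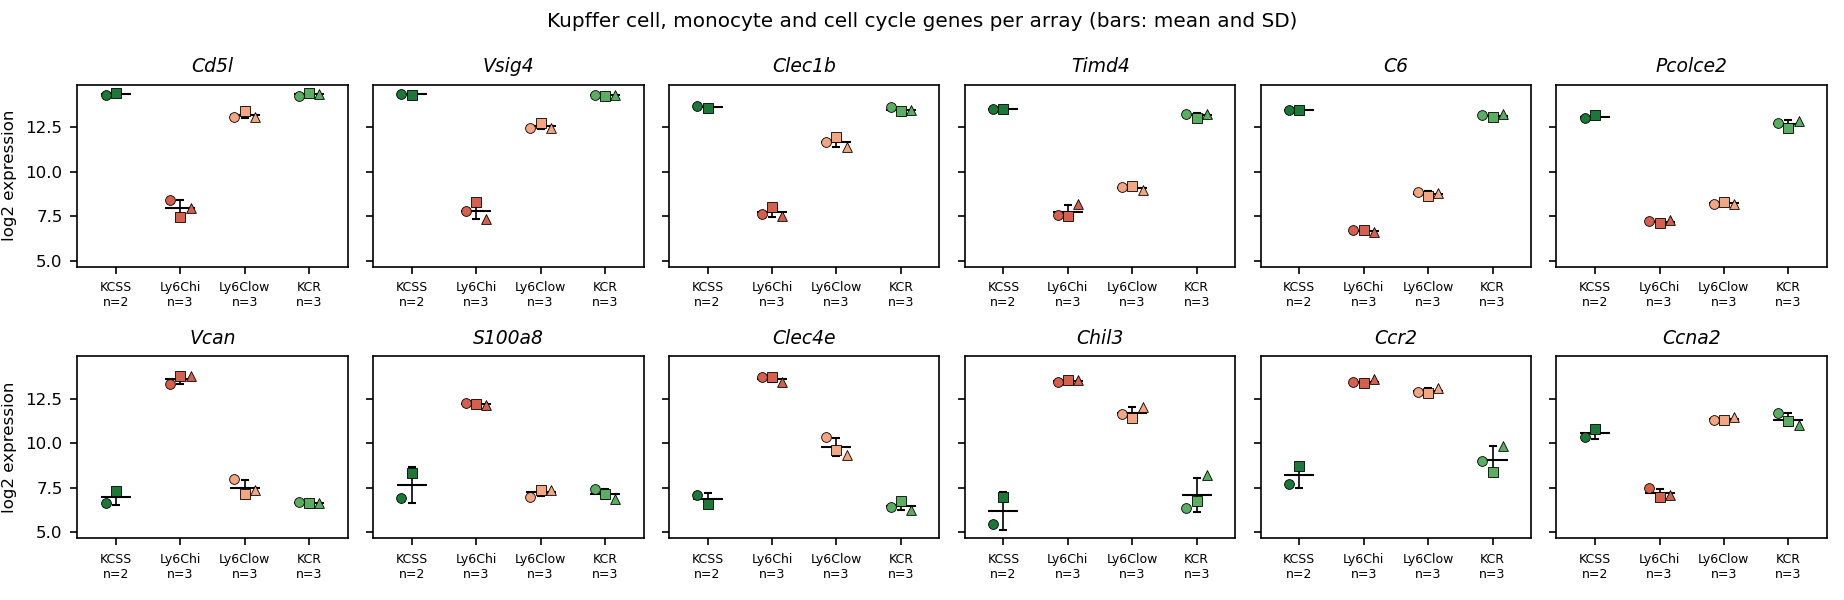
Log2 expression of 12 genes on each array, with marker shape for the replicate number and bars for the mean and SD of KCSS (n = 2), Ly6Chi, Ly6Clow and KCR (n = 3 each). Cd5l averages 13.20 in Ly6Clow and 7.95 in Ly6Chi, whereas C6 averages 8.77 in Ly6Clow and 13.16 in KCR.

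Kupffer cells at 72 h after the overdose were compared with steady-state Kupffer cells. The profiles lay close together, with a few genes apart. Gpnmb, a transmembrane glycoprotein of phagocytes rich in lysosomes, rose from 8.09 ± 0.08 in KCSS (SD, n = 2) to 12.95 ± 0.50 in KCR (SD, n = 3), a 29.2-fold difference. Cyp2e1, the enzyme that turns acetaminophen into its toxic metabolite in hepatocytes, fell from 9.63 ± 0.27 to 7.65 ± 0.10. Whether the RNA of the genes lower in KCR came from Kupffer cells or from hepatocytes was not tested. limma called 13 probe sets (3 higher and 10 lower) in 12 genes, with 3640 probe sets at an unadjusted p under 0.05. With the replicate block 8 were called in 7 genes (1 higher and 7 lower), with 7 of the probe sets shared and 4642 at an unadjusted p under 0.05. Gpnmb led at 4.87 ± 0.28 (adjusted p = 0.000638), and it stayed called without each array in turn, as did the carboxylesterase Ces1c (-1.68 ± 0.12, adjusted p = 0.00193) and the paraoxonase Pon1 (-1.19 ± 0.07, adjusted p = 0.000638). Without the number 1 arrays Gpnmb alone was called, and the adjusted p of Ces1c was 0.0699 and that of Pon1 0.141 (0.00041 and 0.000171 to 0.255 over the alternatives). Cyp2e1 differed by -1.99 ± 0.16 (adjusted p = 0.00595), with an adjusted p of 0.0526 without KCR replicate 3 and 0.141 without the number 1 arrays (0.00129 to 0.255 over the alternatives). The macrophage elastase Mmp12 (2.36 ± 0.30, adjusted p = 0.0395) and the collagenase Mmp13 (1.64 ± 0.20, adjusted p = 0.0289) were higher, with adjusted p values of 0.0626 and 0.0663 with the replicate block (0.0125 to 0.431 and 0.00932 to 0.361 over the alternatives). Of the 11 fits without 1 array, Mmp12 was called only in those without Ly6Chi replicate 2 or 3, and Mmp13 only in those without Ly6Chi replicate 1 or 3 (highest adjusted p 0.147 and 0.145, both without KCR replicate 2). Irak3, a brake on Toll-like receptor signalling, was lower by a log2 difference of -1.19 ± 0.12 (adjusted p = 0.017), with an adjusted p of 0.0791 without KCSS replicate 1, 0.0757 without KCSS replicate 2, 0.06 without Ly6Clow replicate 2 and 0.0931 without KCR replicate 3 (0.00309 to 0.361 over the alternatives). Sv2c differed by -1.18 ± 0.12 (adjusted p = 0.017), and Slc10a1, Serpina6, Klrc1 and Kng1 by -1.05 to -1.03, the latter 4 with adjusted p from 0.0626 to 0.0832 with the block. These 5 stayed called without any 1 of the Ly6Chi arrays. They did so too for Sv2c without Ly6Clow replicate 1 or KCR replicate 1, for Slc10a1 without KCSS replicate 1 or KCR replicate 1, for Serpina6 without Ly6Clow replicate 1, for Klrc1 without Ly6Clow replicate 1 or 2, and for Kng1 without KCSS replicate 1. Each other array left out ended their calls, with the highest adjusted p at 0.139 for Serpina6 without KCR replicate 2. The count of 13 fell to 3 without KCR replicate 3 and to 5 without KCR replicate 2, Ly6Clow replicate 2 or Ly6Clow replicate 3. It was 1 without the number 1 arrays and 0 when only these 2 groups were fitted in limma, where 3556 probe sets had an unadjusted p under 0.05.

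**Figure D4:**
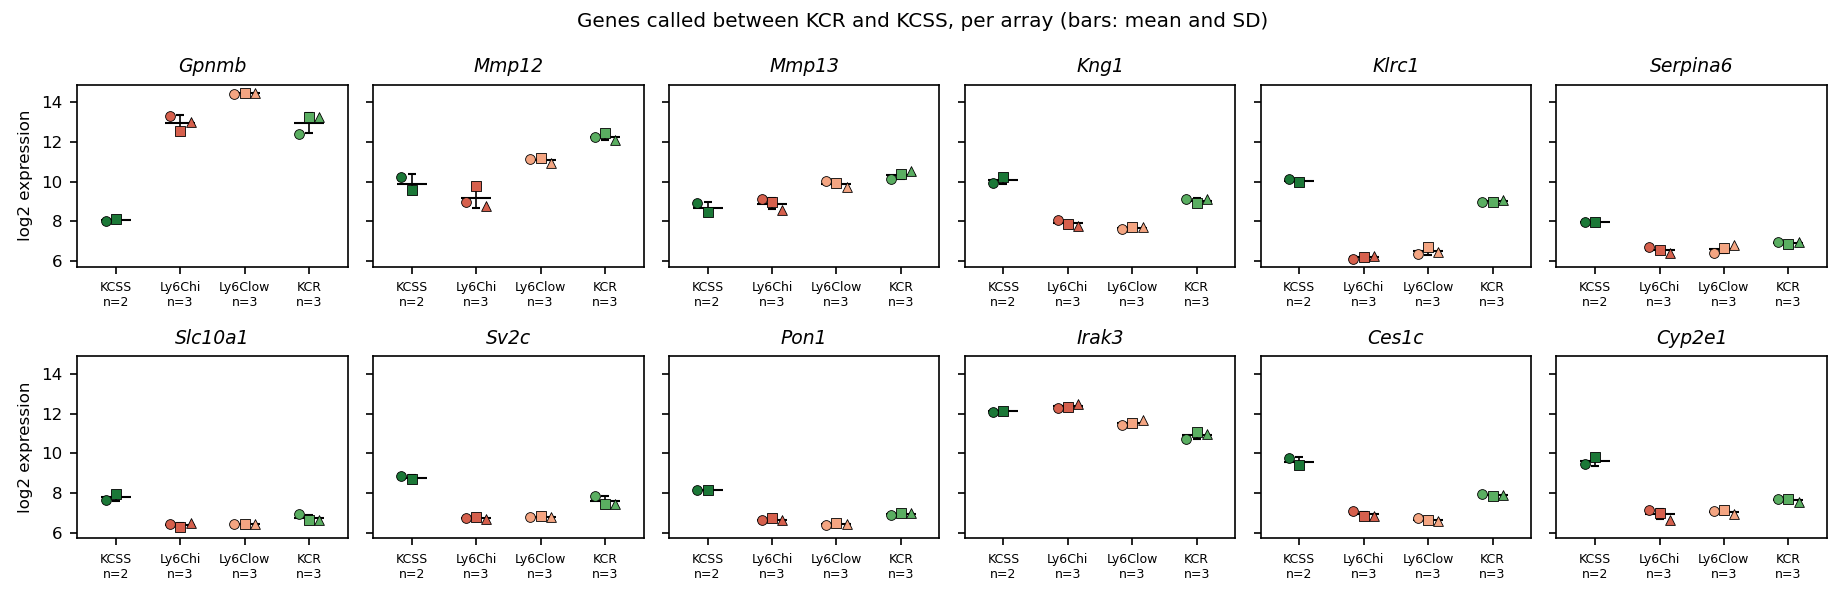
Log2 expression on each array of the 12 genes called between KCR and KCSS, with marker shape for the replicate number and bars for the mean and SD. Gpnmb averages 8.09 in KCSS and 12.95 in KCR, and Cyp2e1 averages 9.63 and 7.65.

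Gene lists shifted little between KCR and KCSS. Of 37 lists 17 passed camera (3 upward and 14 downward), 11 without the number 1 arrays (7 of the 17 and 4 others), and only complement with an estimated correlation. Hepatocyte markers shifted downward with 1 of 18 called, or 3 adjusted over the list alone (median -0.57, adjusted p = 3.27e-11, adjusted p = 0.184 with an estimated correlation). Their median was -0.87 without KCSS replicate 1, -0.28 without KCSS replicate 2 and -0.90 without the number 1 arrays. Cyp2e1 was the member called. Ces1c, Pon1, Slc10a1, Serpina6 and Kng1, also called lower, are not in that list, and the source of their RNA was not tested. Complement genes shifted downward with 0 of 18 called in limma and 7 at an unadjusted p under 0.05, or 1 called adjusted over the list alone and 1 with the replicate block (median -0.23, adjusted p = 6.43e-06, adjusted p = 0.0456 with an estimated correlation). Trem2-associated genes shifted upward with 1 of 16 called, Gpnmb, or 5 adjusted over the list alone (median 0.23, adjusted p = 0.000135, adjusted p = 0.239 with an estimated correlation). MHC class II genes had a median of -0.29 with 0 of 14 called and 3 at an unadjusted p under 0.05 (adjusted p = 0.000917, adjusted p = 0.0939 with an estimated correlation). Toll-like receptors and adaptors, with Irak3 called of 19, had a median of -0.13 (adjusted p = 0.00194, adjusted p = 0.0939 with an estimated correlation). Kupffer cell markers had a median of -0.15 with 0 of 22 called and 3 at an unadjusted p under 0.05 (adjusted p = 0.00573, adjusted p = 0.239 with an estimated correlation), and their adjusted p was 0.0519 without the number 1 arrays, 0.103 without dim probe sets and 0.0937 with dim genes out of the background (7.28e-05 to 0.239 over the alternatives).

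Other shifts between KCR and KCSS rested on single arrays or on the number 1 arrays, and limma called none of their members. Cell cycle genes shifted upward with 0 of 35 called and 10 at an unadjusted p under 0.05 (median 0.32, adjusted p = 1.15e-07, adjusted p = 0.422 with an estimated correlation). Their median was 0.18 without KCR replicate 1, 0.15 with array weights and 0.08 without the number 1 arrays (adjusted p = 0.908, and 3.07e-15 to 0.908 over the alternatives). Dissociation and heat shock genes shifted downward with 0 of 20 called and 6 at an unadjusted p under 0.05 (median -0.47, adjusted p = 1.95e-07, adjusted p = 0.245 with an estimated correlation). Their median was -0.15 without KCSS replicate 1, -0.78 without KCSS replicate 2, -0.29 without KCR replicate 1 and -0.05 without the number 1 arrays (adjusted p = 0.111, and 8.11e-12 to 0.245 over the alternatives). Inflammatory cytokines had a median of -0.35, with 3 of 20 at an unadjusted p under 0.05 (adjusted p = 0.00637, adjusted p = 0.481 with an estimated correlation). That adjusted p was 0.0559 with the replicate block, 0.0663 with only the 2 groups fitted, 0.0898 without dim probe sets and 0.0804 with dim genes out of the background. The median was -0.23 with the block, 0.04 without KCSS replicate 1 (adjusted p = 0.225) and 0.07 without the number 1 arrays (adjusted p = 0.735, and 4.13e-05 to 0.735 over the alternatives). Macrophage transcription factors had a median of -0.17, with 4 of 30 at an unadjusted p under 0.05 (adjusted p = 0.000843, adjusted p = 0.209 with an estimated correlation). It was -0.09 without KCSS replicate 1, -0.10 with array weights and -0.03 without the number 1 arrays (adjusted p = 0.061, and 0.000221 to 0.209 over the alternatives). Sinusoidal endothelial markers had a median of -0.36, with 1 of 20 at an unadjusted p under 0.05 (adjusted p = 0.0137, adjusted p = 0.686 with an estimated correlation). Their adjusted p was 0.0801 without KCSS replicate 1, 0.0873 without KCR replicate 1 and 0.114 without KCR replicate 3, where the median was -0.19, and 0.123 without dim probe sets and 0.116 with dim genes out of the background (3.86e-05 to 0.686 over the alternatives). The median was -0.60 without KCR replicate 2 and -0.17 without the number 1 arrays (adjusted p = 0.233). The oxidative phosphorylation list had a median of 0.13, with 4 of 27 at an unadjusted p under 0.05 (adjusted p = 0.0398, adjusted p = 0.62 with an estimated correlation). That median was -0.01 without KCSS replicate 1 (adjusted p = 0.776) and 0.06 without KCR replicate 2 (adjusted p = 0.466), and 0.21 without KCSS replicate 2 or KCR replicate 1. The call was also lost without KCR replicate 3, Ly6Chi replicate 2 or the number 1 arrays (adjusted p = 0.156, 0.0549 and 0.124), and with median centring, only the 2 groups fitted or trend and robust settings (0.102, 0.0646 and 0.0526, and 3.15e-05 to 0.776 over the alternatives).

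The sort gate, clearance, iron, Fc receptor and oxidant defence lists had medians from -0.19 to -0.06 between KCR and KCSS, with 0 members called in limma and 2 to 4 each at an unadjusted p under 0.05, and 1 of 19 iron genes lower adjusted over the list alone (adjusted p from 0.00517 to 0.04, adjusted p from 0.184 to 0.254 with an estimated correlation). Without KCSS replicate 2 their adjusted p values were 0.104, 0.161, 0.105, 0.0543 and 0.348. The call was also lost for the sort gate list without KCR replicate 2 (0.0631), and for the clearance, Fc receptor and oxidant defence lists without KCR replicate 1 (0.15, 0.0592 and 0.109). Without the number 1 arrays the sort gate, clearance and Fc receptor lists had adjusted p values of 0.061, 0.0938 and 0.111. Each of the 5 lost the call without dim probe sets (0.115, 0.186, 0.0515, 0.413 and 0.166) and with dim genes out of the background (0.114, 0.312, 0.0804, 0.116 and 0.177). All but the iron list lost it with array weights (0.074, 0.074, 0.0517 and 0.101). Over the alternatives the adjusted p of the 5 lists reached at most 0.184, 0.312, 0.254, 0.413 and 0.348, and at least 0.0104, 0.00368, 0.000583, 0.00594 and 0.00239. The Fc receptor median of -0.06 was -0.14 without KCSS replicate 1, -0.09 without KCR replicate 2 and -0.11 without KCR replicate 3. The other 20 lists did not pass (adjusted p from 0.121 to 0.953), among them matrix proteases, with Mmp12 and Mmp13 as the members called of 20 and neither called with the replicate block, and inflammatory monocyte markers (median -0.13, adjusted p = 0.424). The monocyte list passed with a median of -0.21 without KCSS replicate 1 (adjusted p = 0.00239) and of -0.23 without the number 1 arrays (adjusted p = 0.000752, and 0.000752 to 0.996 over the alternatives), and its median was 0.20 without KCSS replicate 2. T and NK cell markers (0.08, adjusted p = 0.646) passed at -0.22 without KCSS replicate 1, 0.24 without KCSS replicate 2 and -0.18 without the number 1 arrays (4.72e-05 to 0.977 over the alternatives). Neutrophil (-0.25) and stellate cell markers (0.22) passed without the number 1 arrays, and both also without KCSS replicate 1 or KCR replicate 1 (0.00312 to 0.899 and 0.00975 to 0.588). Chemokines and sex-linked genes passed without KCSS replicate 2, proteases without KCR replicate 1 and core macrophage genes without Ly6Chi replicate 2. In 4 of the 20, the lysosomal, growth factor, lipid and chemokine receptor lists, the median, the mean and camera's direction differed in sign.

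The place of Ly6Clow between monocytes and Kupffer cells was described over the 1794 genes called between Ly6Chi and KCSS. On a scale where the Ly6Chi mean is 0 and the KCR mean is 1, the 3 Ly6Clow arrays lay at 0.604 ± 0.087 (SD, n = 3), from 0.549 to 0.705. The 1172 genes higher in Kupffer cells gave 0.589 ± 0.14 and the 622 genes higher in Ly6Chi gave 0.627 ± 0.015. The scale carries no test. Most endothelial and hepatocyte markers are among the 1172 genes, so the scale does not rest on Kupffer cell genes alone. Without Ly6Clow replicate 2 the position was 0.543. Ehd3 (12.59) and Ms4a1 (10.14), markers of other cell types, stood highest there among the Ly6Clow arrays. The Ly6Chi arrays served both to select the genes and to set an end point.

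Ly6Chi monocytes and steady-state Kupffer cells differed in monocyte, Kupffer cell and complement genes. Chil3, Clec4e and Vcan were higher by 7.33 ± 0.55, 6.75 ± 0.28 and 6.64 ± 0.26, and C6, Vsig4 and Cd5l were lower, at -6.77 ± 0.09, -6.54 ± 0.22 and -6.42 ± 0.23 (adjusted p from 2.83e-09 to 3.09e-05). limma called 2315 probe sets, 888 higher and 1427 lower. Kupffer cell markers were lower for 20 of 22 genes (adjusted p = 2.16e-23, adjusted p = 0.00828 with an estimated correlation), including the lectin Clec4f (-6.36 ± 0.11). Inflammatory monocyte markers were higher for 14 of 17 (adjusted p = 3.02e-12, adjusted p = 0.0391 with an estimated correlation). Growth factors, with Pdgfc at -4.84 ± 0.13 and Thbs1 at 5.32 ± 0.26, were lower for 10 of 22 and higher for 2 (adjusted p = 0.000167, adjusted p = 0.036 with an estimated correlation). Clearance, complement and MHC class II genes were lower for 12 of 24, 12 of 18 and 6 of 14 (adjusted p = 3.12e-07, 4.4e-05 and 4.4e-05, adjusted p = 0.00988, 0.0254 and 0.0254 with an estimated correlation), and complement had 3 higher. Kupffer cells were sorted with MHC class II and Ly6Chi without it, so the MHC class II result follows the gates. Hepatocyte markers were lower for 14 of 18, or 15 adjusted over the list alone (adjusted p = 1.5e-10, adjusted p = 0.186 with an estimated correlation), and endothelial markers for 18 of 20 (adjusted p = 4.42e-10, adjusted p = 0.329 with an estimated correlation). Neutrophil markers were higher for 6 of 18 and lower for 1 (adjusted p = 0.00311, adjusted p = 0.329 with an estimated correlation), led by Mmp8 (6.03 ± 0.29). Stellate cell, T and NK cell and dendritic cell markers were lower for 4 of 18, 5 of 20 and 3 of 18, or 4, 5 and 4 adjusted over the list alone, and higher for 1, 1 and 2 (adjusted p = 0.0175, 0.00146 and 0.032, adjusted p = 0.358, 0.487 and 0.332 with an estimated correlation). B cell markers were lower for 2 of 15, or 3 adjusted over the list alone and 4 with the replicate block (adjusted p = 0.0158, adjusted p = 0.538 with an estimated correlation).

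Ly6Chi monocytes at 24 h and recovered Kupffer cells at 72 h differed at 2282 probe sets, 1027 higher and 1255 lower in Ly6Chi. Clec4e, Vcan and Chil3 stood 7.14 ± 0.25, 6.97 ± 0.23 and 6.42 ± 0.50 higher, and Vsig4, C6 and Cd5l differed by -6.48 ± 0.20, -6.47 ± 0.08 and -6.41 ± 0.21 (adjusted p from 1.56e-09 to 3.05e-05). Kupffer cell markers were lower for 19 of 22 (adjusted p = 6.19e-21, adjusted p = 0.0117 with an estimated correlation) and clearance genes for 12 of 24 (adjusted p = 1.72e-06, adjusted p = 0.0141 with an estimated correlation). Cell cycle genes were lower for 28 of 35 (adjusted p = 6.23e-21, adjusted p = 0.176 with an estimated correlation), among them Mki67 (-2.94 ± 0.16). Monocyte markers were higher for 15 of 17 (adjusted p = 3.55e-14, adjusted p = 0.0532 with an estimated correlation). Dissociation and heat shock genes were higher for 9 of 20 (adjusted p = 1.72e-06, adjusted p = 0.26 with an estimated correlation), with Ier3 at 2.55 ± 0.17. Markers of other cell types differed as well. Sinusoidal endothelial markers were lower in Ly6Chi for 18 of 20 and higher for 1, or 19 and 1 adjusted over the list alone (adjusted p = 3.22e-08, adjusted p = 0.313 with an estimated correlation), with Ehd3 at -3.57 ± 0.51 and Dnase1l3 at -3.83 ± 0.42. Hepatocyte markers were lower for 6 of 18 (adjusted p = 3.05e-05, adjusted p = 0.307 with an estimated correlation), with Alb at 11.57 ± 0.37 in Ly6Chi and 13.17 ± 0.087 in KCR (SD, n = 3 each). Neutrophil markers were higher for 6 of 18 (adjusted p = 2.37e-05, adjusted p = 0.186 with an estimated correlation), with Slpi at 4.17 ± 0.15 and Il1r2 at 11.72 ± 1.8 in Ly6Chi and 6.72 ± 0.26 in KCR. B cell markers were lower for 4 of 15, or 5 adjusted over the list alone (adjusted p = 0.00731, adjusted p = 0.55 with an estimated correlation). Among them Ms4a1 differed by -2.35 ± 0.52 (adjusted p = 0.0122, 0.0503 without KCR replicate 2, and 0.00205 to 0.0503 over the alternatives). Stellate cell, T and NK cell and dendritic cell markers were lower for 4 of 18, 5 of 20 and 4 of 18 and higher for 2, 1 and 2 (adjusted p = 0.000977, 0.000554 and 0.0192, adjusted p = 0.234, 0.455 and 0.288 with an estimated correlation), with Clec9a, itself bright in Kupffer cells, at -5.26 ± 0.26.

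Ly6Clow macrophages differed from steady-state Kupffer cells at 849 probe sets, 349 higher and 500 lower. Gpnmb, Chil3 and Atp6v0d2 were higher by 6.37 ± 0.28, 5.51 ± 0.55 and 4.90 ± 0.49 (adjusted p = 2.77e-06, 0.000437 and 0.000446), and Cxcl13, Pcolce2 and Il6 differed by -5.73 ± 0.20, -4.88 ± 0.12 and -4.78 ± 0.80 (adjusted p = 8.22e-07, 2.21e-07 and 0.00796). The adjusted p of Il6 was 0.087 without KCSS replicate 1 and 0.201 without the number 1 arrays (0.00125 to 0.201 over the alternatives). Kupffer cell markers were lower for 12 of 22, or 14 adjusted over the list alone (adjusted p = 1.95e-22, adjusted p = 0.00943 with an estimated correlation). Complement genes were lower for 7 of 18 and higher for 1, or 8 and 1 adjusted over the list alone (adjusted p = 7.12e-05, adjusted p = 0.0304 with an estimated correlation), with C2 at -3.88 ± 0.17 and C4b at -3.72 ± 0.32. Clearance genes were lower for 7 of 24, or 8 lower and 1 higher adjusted over the list alone, and 7 lower and 1 higher with the replicate block (adjusted p = 1.47e-05, adjusted p = 0.0214 with an estimated correlation). Trem2-associated genes were higher for 6 of 16 (adjusted p = 7.25e-07, adjusted p = 0.2 with an estimated correlation), with Cd63 at 4.35 ± 0.51. Hepatocyte markers were lower for 13 of 18 (adjusted p = 4.77e-18, adjusted p = 0.124 with an estimated correlation). Endothelial markers were lower for 2 of 20, or 12 adjusted over the list alone (adjusted p = 6.21e-08, adjusted p = 0.5 with an estimated correlation). T and NK cell markers shifted downward with 0 of 20 called in limma and 8 at an unadjusted p under 0.05 (adjusted p = 0.0305, adjusted p = 0.741 with an estimated correlation). In the 3 secondary comparisons, 4 lists between Ly6Chi and KCSS, 1 between Ly6Chi and KCR and 7 between Ly6Clow and KCSS differed in sign between median, mean and camera, and none of these passed.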

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

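The fits without the number 1 arrays, with number 1 against the others as a block, and without sex-linked probe sets, the filter on genes for the position, and the shares against single KCSS arrays, were chosen after the data were seen. Where a list passed under neither setting, a change of its direction was not counted as a reversal, which covers 105 of 2883 list results. The log2(value + constant) scale and an unmoderated camera were not run, since the values are already log2 and camera has no such fit here. The cause was not tested for any change below, except where fewer arrays or another threshold makes it by construction.

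Probe sets called between Ly6Clow and Ly6Chi ranged from 1115 to 1472 over the arrays left out in turn, and from 495 to 669 for Ly6Clow and KCR, 662 to 926 for Ly6Clow and KCSS, 1958 to 2458 for Ly6Chi and KCSS, and 2106 to 2389 for Ly6Chi and KCR. These 5 counts stayed within 1.5 times under every alternative except no fold minimum, which gave 4601, 1599, 2291, 6591 and 7278. Between KCR and KCSS the 13 calls became 0 with only the 2 groups fitted (3556 at an unadjusted p under 0.05 in limma), 8 with the replicate block, 4 without moderation, 20 with array weights, 23 with no fold minimum, 4 at an adjusted p of 0.01 and 1 without the number 1 arrays, and 3 to 17 over the arrays left out. They stayed at 13 without sex-linked probe sets. Median array correlations were 0.9695 within and 0.9207 between groups without dim probe sets. The position of Ly6Clow stayed within its SD, at 0.594 to 0.654 under other settings and 0.543 to 0.658 over the arrays left out. The added filter, used at first and then set beside the planned version, gave 0.608.

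With an estimated correlation 2, 2 and 1 lists passed in the main comparisons, against 21, 15 and 17. Between KCR and KCSS 11 passed without dim probe sets, 11 without the number 1 arrays, 11 with dim genes out of the background and 6 in fry. Of the lists that did not pass, 3, 7 and 8 passed in at least 1 camera alternative, each of them without an array or the number 1 arrays. The replicate block also passed the interferon (adjusted p = 0.0199) and stellate cell lists (adjusted p = 0.0288) between Ly6Clow and KCSS, and called Mmp9 there (adjusted p = 0.0453); apart from these and the changes given beside the results, it changed no other call of a named gene or list. Lists of the 3 secondary comparisons were run with the block, with an estimated correlation and in fry, and not under the other alternatives.

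Reversals, scored by the sign of the log2 difference for genes and by camera's direction for lists, were these. The median of the inflammatory cytokine list between KCR and KCSS also turned, though camera's direction did not, without KCSS replicate 1 and without the number 1 arrays (0.0441 and 0.0673, against -0.352). In fry the matrix protease list turned between Ly6Clow and Ly6Chi (median -0.208, against the direction of fry). Quantile normalization turned Ptprc (-0.02741) between Ly6Chi and KCSS and Fcgr1 (-0.007948) between Ly6Chi and KCR, median centring turned Fcgr1 (0.01126) between Ly6Chi and KCSS, and the replicate block turned Ptprc (-0.02156) there. Without the number 1 arrays, between KCR and KCSS, Xist (0.1941), Kdm5d (-0.0711), the cell cycle list (0.0795, with camera pointing down) and the T and NK list (-0.183) turned. H2-Ab1 (0.0011) and Xist (0.02581) turned between Ly6Clow and KCSS, and Fcgr1 (0.00995), Kdm5d (-0.2477) and Uty (-0.548) between Ly6Chi and KCSS. Over the arrays left out in turn, the ranges of results that turned were these, with the turn without KCSS replicate 1 unless another is named. Between KCR and KCSS they were -6.433 to 0.1435 for Xist, -0.02463 to 3.615 for Kdm5d, -0.00813 to 0.215 for the oxidative phosphorylation list and -0.216 to 0.24 for the T and NK list. Between Ly6Clow and KCSS the range was -6.524 to 0.05269 for Xist. Between Ly6Chi and KCSS they were -0.06643 to 0.01127 for Fcgr1, -0.1363 to 3.503 for Kdm5d and -0.4695 to 4.669 for Uty. Ptprc between Ly6Chi and KCSS ranged from -0.05347 to 0.104 and turned without KCSS replicate 2 and Ly6Chi replicates 1 and 3, and Xist between Ly6Clow and KCR ranged from -0.1708 to 0.03982 and turned without KCR replicate 3. Of named genes called, 67 of 78 stayed called without each array between Ly6Clow and Ly6Chi, 31 of 38 between Ly6Clow and KCR and 3 of 12 between KCR and KCSS.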

Other observations

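The tests on carried-over cells, the number 1 arrays, the replicate numbers, the shares of hepatocyte markers, the genes of Ly6Clow without single arrays and the splits of the arrays were chosen after the results they bear on were seen, while both tests of hepatocyte zones were set before. The genes named in the next paragraph were chosen after their values were seen.

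Some genes marked Ly6Clow macrophages against all 3 other groups. Called higher against each were 26 genes. They included the costimulatory receptor Cd28 (smallest of the 3 log2 differences 2.68), the lectin Cd209a (2.43), the proton pump subunit Atp6v0d2 (2.39), the fatty acid carrier Fabp5 (1.60), Gpnmb (1.49, at 14.45 ± 0.02 SD on the log2 scale) and the integrin Itga6 (1.79). Called lower against each were 6 genes, namely Il6, the chemokine Ccl24, Clec4n, Ms4a8a, Fgb and the costimulatory ligand Cd86 (differences of -1.03, -1.55 and -1.92 against Ly6Chi, KCR and KCSS). Fgb is in the hepatocyte list, and Il6 and Fgb lay below the dim limit in Ly6Clow (6.13 and 7.74). Without each array in turn 13 of the 26 and 2 of the 6 (Ccl24 and Clec4n) stayed called against all 3 groups, and without the number 1 arrays 16 and 3. Fabp5, Cd28, Itga6 and Gpnmb kept every call in these fits. Atp6v0d2 lost the call against KCR without Ly6Clow replicate 3 (adjusted p = 0.0737), and Cd209a lost all 3 without the number 1 arrays (adjusted p = 0.0571, 0.0602 and 0.102 against Ly6Chi, KCR and KCSS, the highest over its alternatives, the lowest being 0.000622, 0.000262 and 0.000296). Fgb fell below the fold minimum against Ly6Chi without Ly6Chi replicate 2 (-0.96) or the number 1 arrays, and against KCR it was not called without Ly6Clow replicate 1, KCR replicate 1, KCR replicate 3 or the number 1 arrays (adjusted p from 0.057 to 0.102). Cd86 was below the fold minimum against Ly6Chi without Ly6Chi replicate 1 or Ly6Clow replicate 3 (-0.98 and -0.86), and Ms4a8a was not called against KCR without KCR replicate 1 (-0.98) or without the number 1 arrays. Il6 differed by -3.07 from KCR with an adjusted p of 0.0463, and of 11 fits without 1 array only 2, those without Ly6Chi replicate 2 or 3, called it against all 3 groups (adjusted p against KCR up to 0.162, and 0.203 without the number 1 arrays).

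Kupffer cell markers were higher in Ly6Clow than in Ly6Chi. If Kupffer cells carried into the sort were the cause, each marker would stand at 1 share of its KCR level, both taken above Ly6Chi on a linear scale, and bright Kupffer cell genes set that share at no more than 4.5% (percentile 10 of the highest shares of 25 genes). Of 16 called markers, 13 had a lowest share above this, with mean shares such as 55.3% for Slc40a1, 44.4% for Cd5l, 29.6% for Vsig4 and 9.87% for Clec4f. This argues against carry-over for the 13 where signal is proportional to RNA. Whether it is so for markers this bright was not tested (Slc40a1 at 14.16 and Cd5l at 14.36 in KCR). Timd4, C6 and Pcolce2 (mean shares 3.71%, 3.71% and 2.36%) lay below it. For these 3 the shares cannot tell carry-over from expression, though the Ly6Clow gate required GFP, which Kupffer cells were sorted without. An additive array batch that follows the replicate number would cancel here, since both groups hold numbers 1, 2 and 3. The list's medians of 1.63, 1.85 and 1.52 within those numbers therefore cannot test it. They show only that the rise was present within each number. A change in the monocyte-derived cells between 24 h and 72 h, which the groups name, stays open and was not tested.

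Gpnmb, Mmp12 and Mmp13 were higher in KCR than in KCSS. Ly6Clow macrophages in the KCR gate could bring at most 2.85% of their level above KCSS, by the same percentile of 6 bright Ly6Clow genes, and the GFP-negative gate would remove them. That limit rests on F13a1 and Cx3cr1 (highest shares 2.67% and 3.02%), and the gate itself selects against Cx3cr1. Mean shares were 3.92% and 5.22% for Ccr2 and Emp1, but 21.9% and 19.8% for Cd63 and Atp6v0d2. The share of Gpnmb averaged 35.9% and ran from 22.8% to 42.6% over the KCR arrays. Cd63 and Atp6v0d2 reached at most 32% and 33.6%. Carried-over cells would bring every gene at 1 share, yet F13a1, Ccr2 and Emp1 reached at most 2.67%, 8.32% and 8.52%. Where signal is proportional to RNA, these values argue against carried-over Ly6Clow cells as the whole source of Gpnmb. A part from such cells is not excluded. Mean shares of Mmp12 and Mmp13 were 320% and 163%, above the Ly6Clow level itself, which argues against carry-over for these genes. Among the number 1 arrays only KCSS replicate 1 differed in its sex-linked genes. Gpnmb was 5.10 higher without the number 1 arrays and 4.35 and 5.11 higher within numbers 1 and 2 (adjusted p from 8.23e-05 to 0.255 over the alternatives). These values argue against a batch of those arrays, or the sex-linked difference of KCSS replicate 1 among them, as its cause. Mmp12 and Mmp13 were not called without those arrays (adjusted p = 0.431 and 0.153, and 0.0125 to 0.431 and 0.00932 to 0.361 over the alternatives), but their differences of 2.36 ± 0.30 and 1.64 ± 0.20 were then 2.72 ± 0.43 and 1.96 ± 0.19 (SE), with 1.98 and 1.22 within number 1 and 2.91 and 1.90 within number 2, so the call ended with fewer arrays rather than a smaller difference, which argues against those arrays as the cause here too. The lone KCSS array left is assumed to vary like the other groups, and a response of Kupffer cells to the injury was not tested.

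Hepatocyte markers shifted downward from KCSS to KCR with 1 of 18 called (median -0.57, -0.28 without KCSS replicate 2 and -0.90 without the number 1 arrays, adjusted p = 3.27e-11, adjusted p = 0.184 with an estimated correlation), though parenchymal cells are spun out and the CD45 gate would remove hepatocytes, so RNA or debris taken up from them may be the source (Alb stood at 13.69 in KCSS and 11.57 in Ly6Chi, and the list shares no gene with another). A loss of pericentral hepatocytes, the site of acetaminophen injury, predicted a pericentral fall at least 0.5 larger than the periportal fall; the difference was 0.101 (medians -0.0548 and -0.156), which met the bound set against it. Like falls in every zone predicted medians within 0.25 of each other, which they were, but the contrast of both lists was higher on every KCR array (2.49 to 2.83) than on either KCSS array (2.15 and 2.17, lowest KCSS minus highest KCR -0.683). Both tests were set aside only after these values were seen, because 3 of 16 pericentral and 7 of 15 periportal genes stood above the dim limit and the called gene Cyp2e1 was not in the list, so neither reading is decided, and changed hepatocyte expression was not tested. A test picked afterwards asked whether all hepatocyte transcripts fell by the same share. It took the 14 markers called lower in Ly6Chi than in KCSS, with shares of the KCSS level above the Ly6Chi mean. On every KCR array 8 of the 14 lay below albumin's lowest share of 57.1%. Of these, 4 (Cyp2e1, Apoa2, Fgg and Fgb) also did so against each KCSS array alone (highest share of Cyp2e1 15.1% and 11.0%, lowest of Alb 59.4% and 54.8%). This argues against a uniform loss for these 4 where signal is proportional to RNA. Ly6Chi held more Fgb than Ly6Clow (8.83 and 7.74), as it did Fgg (8.46, and 7.61 to 7.80 on the Ly6Clow arrays). The low shares of both thus depend on Ly6Chi as the base, and no other base was tried.

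Calls were also counted over splits of the 6 arrays of a comparison. For Ly6Clow and Ly6Chi, Ly6Clow and KCR, and Ly6Chi and KCR, 1 of 10 splits, the real one, called as many as 1327, 601 and 2282 probe sets in limma. The highest of the others called 0 in each, including those that part all pairs of numbers, as 4 of the 10 do, and these others had at most 3656, 2324 and 2431 probe sets at an unadjusted p under 0.05. With 10 splits the share cannot be under 0.1. Each other split also holds arrays of both groups on either side. The group difference then enters the spread and lowers the calls. The splits therefore cannot tell how many calls would arise without a group difference.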
